A study of Bemisia tabaci with 2 samples.

How the data were processed

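The samples were adult females of Bemisia tabaci MEAM1 that had newly emerged from TYLCCNV-infected or from mock-inoculated tobacco, per the labels' protocols. Parents reared on cotton laid eggs for 72 h, and their progeny developed at 27 °C with 14 h light, 10 h dark and 70% relative humidity. About 1000 females per group were pooled. Messenger RNA was bound to oligo(dT) beads and the cDNA was digested with NlaIII, which cuts at CATG, per the labels' protocols. An adapter with an MmeI site then gave tags of 21 bases including CATG, and these were amplified by PCR and sequenced on an Illumina Genome Analyzer II.

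The deposited values are raw counts, the copy number of each different read per the file headers, with no normalization. Each read had 35 bases, made of 17 tag bases and the same 18 bases of the 3' adapter, TCGTATGCCGTCTTCTGC. That end was identical in every read of both files, and no sequence was repeated within a file. Base-quality filters and any mapping to genes are not given in the sources used here. Tags with an unread base made up 0.208% of the library from infected plants and 0.216% of the healthy one, and were kept.

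Groups were taken from the growth condition in the labels, with 1 library per group. No test of conditions was made, and no p-value was computed for a difference between conditions. The fold of a tag was its count over the total of the library from virus-infected tobacco, divided by the same share in the healthy tobacco library. Its 95% interval was the exact conditional binomial (Clopper-Pearson) interval. A tag was measured at a summed count of at least 10. It was called higher or lower at a fold of at least 2 with an interval excluding 1. A count of 0 was replaced by a floor of 3 counts in that library. These choices were made before the data were examined.

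The reference table used here gave 14920 genes and no sequences, so tags were not matched to genes. The rule written for genes was therefore applied to tags, as foreseen for that case, and 28 gene lists fixed beforehand were not computed. The planned rule named the 2 higher and the 2 lower tags with the largest conservative bound, the end of the interval nearer to 1, and the 5 most abundant tags. All other tags were chosen after their values were seen. Of these, the 10 higher and 10 lower tags came from tags with at least 1000 counts and the largest conservative bounds. Excluded there were tags ending in at least 4 bases of an element, with 8 or more A in a row, with an unread base, or starting with the complement of the 5' adapter. Tags 1 mismatch from a tag at least 50 times as abundant were also excluded. The library-specific elements were found in the tags themselves, and the adapter sequence came from general knowledge of the platform.

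Tests of explanations were chosen after the data were seen, except that scaling by TMM and by median of ratios was planned. The test of inserts joined to an element replaced the share of tags ending in it, since the elements were found in these tags. The test of cutting sites close to the poly(A) tail was also rewritten after its medians were known. Its first form used the median log2 fold of tags whose A run stopped before the last base, 0.60, and could not have excluded the explanation. Its final form used the difference between tags whose run reached the last base and those whose run did not. Both forms left the question open.

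Alternatives planned before the data were examined were TMM factors (edgeR 4.0.16), median of ratios size factors (DESeq2 1.42.0), other count minimums, removal of tags counted once, a fold of 1.5, an interval wholly beyond 2-fold, and a 2-fold difference with a q under 0.001 in Fisher's exact test. The TMM factors were computed against the totals of measured tags but applied to the full library totals, so that scaling was not a standard TMM scaling. Alternatives added later were totals without the most abundant tag, removal or merging of tag classes, tags cut to 14 bases, and a correction by G and C content. Random lists were drawn 10000 times, matched on abundance in 20 bins. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3.

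The rule was tested on simulated data with counting error only. True 4-fold differences were called in 100% of 50 tags in each direction, and true 3-fold differences in 96% of 50 higher and 84% of 50 lower tags. Of 42747 unchanged tags 2.13% were called, and of 7325 with a summed count of at least 100, 0.0137% were called. The interval held the true fold in 96.7% of 42947 tags. The simulation contains no variation between insects or library preparations.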

Results

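Digital gene expression tags were counted in adult females of the whitefly Bemisia tabaci, a sap-feeding insect that transmits begomoviruses. The insects belonged to the MEAM1 (B biotype) cryptic species. A first pool came from tobacco infected with Tomato yellow leaf curl China virus (TYLCCNV), and the other from healthy, mock-inoculated tobacco. Each pool held about 1000 newly emerged females and gave 1 library, so each group had n = 1. No difference below therefore has a replicate check, and each describes these 2 libraries rather than the growth conditions. Insects from infected plants differed both in host plant state and in access to virus, and the design does not separate these.

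The library from virus-infected tobacco held 3666216 tags of 307171 different sequences. The library from healthy tobacco held 3503061 tags of 258848 different sequences. In total 456922 different tags were seen, and 109097 of them occurred in both libraries. These shared tags made up 92.8% of the virus-infected tobacco library and 94.5% of the healthy tobacco library. Tags counted once made up 65.5% of the different tags but 5.49% of all tags in the library from infected plants. In the healthy tobacco library the corresponding values were 64.1% and 4.74%. The floor of 3 counts set for a count of 0 equalled 0.818 tags per 1000000 in the library from infected plants and 0.856 in the healthy one. The upper ends of the exact 95% intervals of a count of 0 were 1.01 and 1.05 tags per 1000000. Intervals and floors cover counting error only. They treat counts as independent, but tags amplified by PCR are not independent molecules, so the intervals may be too narrow even for counting error.

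The comparison of the libraries addressed which tags differ in abundance between whiteflies from virus-infected and from healthy tobacco. Results are given by tag, written as the 17 bases that follow the CATG site, because tags were not matched to genes here. Whether a tag came from a whitefly transcript or from another source was therefore not tested. Several tags may come from the same transcript, so numbers of tags are not numbers of transcripts. The most abundant tag, ATCTGAGTTCAGACCGG, was 2.37-fold lower in the library from infected plants (95% interval 2.36 to 2.38). It took 7.41% of that library (7.39 to 7.44) and 17.6% of the healthy one (exact Clopper-Pearson intervals for shares and folds). Whether this tag came from a messenger RNA or from ribosomal RNA was not determined here, and the library totals used for scaling include it. Among other abundant tags, GACATTGTCTCCCTCAA was 9.41-fold higher in the library from infected plants (9.12 to 9.72), at 11052 against 1174 tags per 1000000. The tag GATATTGTATCAATAAT was 8.40-fold higher (8.14 to 8.67), at 10477 against 1248 tags per 1000000.

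Of 41794 tags with a summed count of at least 10, 4568 were at least 2-fold higher and 4469 at least 2-fold lower in the library from infected plants, each with a counting interval excluding 1. Higher tags were 50.55% of those called. Scaled to totals without the most abundant tag, an alternative chosen after seeing the data, 3562 tags were higher and 5884 lower, and the higher share was 37.7%. That scaling lowered every log2 fold by the same amount (a shift of -0.17). The median log2 fold over measured tags was -0.04 under the main scaling. The higher tags together took 16.2% of the library from infected plants and 4.73% of the healthy one. The lower tags took 10.8% and 27.6%, the most abundant tag included. Among 658 tags with at least 1000 counts, 82 were higher and 64 lower. Most measured tags were sparse: 28724 had summed counts under 50, of which 3033 were higher and 2803 lower. The calls depended on the threshold, with 1334 higher and 955 lower when the whole interval had to lie beyond 2-fold.

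**Figure D1:**
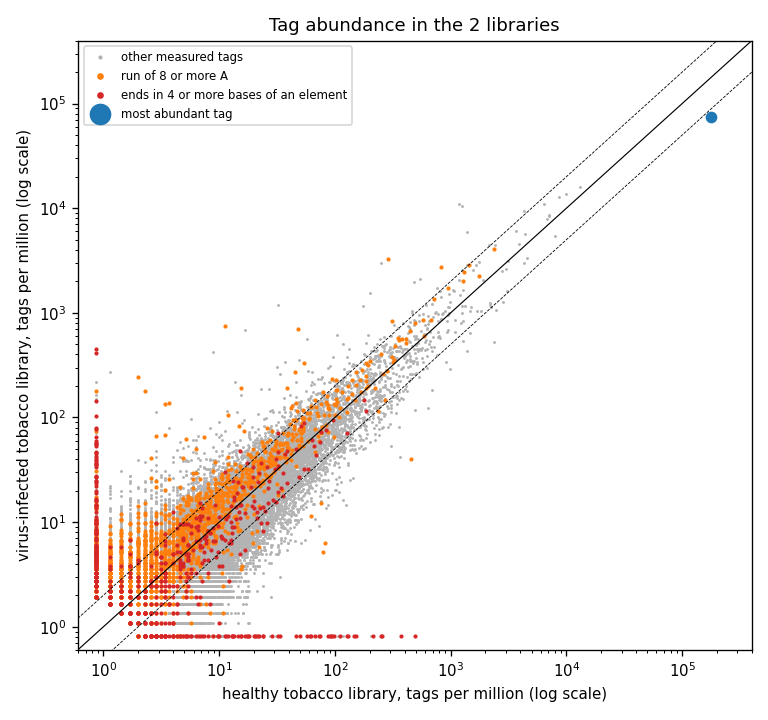
Relative abundance, in tags per 1000000, of each measured tag in the healthy tobacco library (x axis, log scale) and the virus-infected tobacco library (y axis, log scale), 1 library each. The solid line marks equal abundance, the dashed lines mark 2-fold differences, and a count of 0 is drawn at the floor of 3 counts. The most abundant tag lies below the lower dashed line at 2.37-fold lower.

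By counts summed over both libraries, the 4 tags next to the most abundant tag lay within 2-fold between the libraries, each higher in the library from infected plants. TTCCTCAGTTGATCAAA was 1.21-fold higher, with 58107 against 46037 counts, and TAAGATTTATTTGGGCG was 1.38-fold higher. GAACCCAGTTAAAATAA was 1.48-fold higher, and TAATGATTGGTCTAATC was 1.72-fold higher. Without the most abundant tag the totals were 3394437 and 2886600. The 10 most abundant remaining tags then held 11.8% of the library from infected plants and 9.25% of the healthy one.

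A set of 588 tags had at least 1000 counts and none of the sequence features described below. This selection and its tags were chosen after the data were seen. Of these, 70 were higher and 54 lower in the library from infected plants, and 19 were at least 4-fold higher against 4 at least 4-fold lower. These counts hold for the main scaling and were not recomputed. Totals without the most abundant tag would lower every fold and move the balance toward lower tags. The tag given below at 9.92-fold differs by 1 mismatch from a tag with an A run that was 11.3-fold higher. It stayed in the set because its own run is shorter than 8 A and the other tag was less than 50 times as abundant. It may therefore not be independent of the tags with an A run. The largest folds belonged to CGGAATTTGAGATACAC, 47.6-fold higher (33.4 to 70.3), and to GATTAAAAAGATGGAAA, 41.3-fold higher (31.8 to 54.5). GATTAAGAAGATGGAAA was 37.2-fold higher (30.9 to 45.3), with 4401 against 113 counts. GACATCGTCGCCTTAAA was 11.9-fold higher, CTACTAGAAGCTGAAAC 9.69-fold and GGTACTCTTTTATAATT 9.24-fold. AAATCGAAAAAAGAAAA was 9.92-fold higher, and GCTTCCCCTCAACAACA 7.70-fold.

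Among the lower tags of this set, TTTTATTTCATTCAAGG was 5.67-fold lower in the library from infected plants (4.86 to 6.64), and ACGTTGATCCCATTGAG was 5.24-fold lower (4.73 to 5.81). TCCCTCGGAGAATTTGG was 4.38-fold lower and TCCTTTTTCGGTCCCGG 4.14-fold. ATGTCTAACATCTGGTG was 3.82-fold lower, AAAACTGACCATTACAG 3.61-fold and TTAGTTACATATCTCGT 3.56-fold. ACAGTTTTAAAATTTGT was 3.45-fold lower and TGAGAAGTTTAATATGG 3.40-fold. The more abundant TGATTTTAATTATACGT was 3.14-fold lower, with 1600 against 4805 counts.

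**Figure D2:**
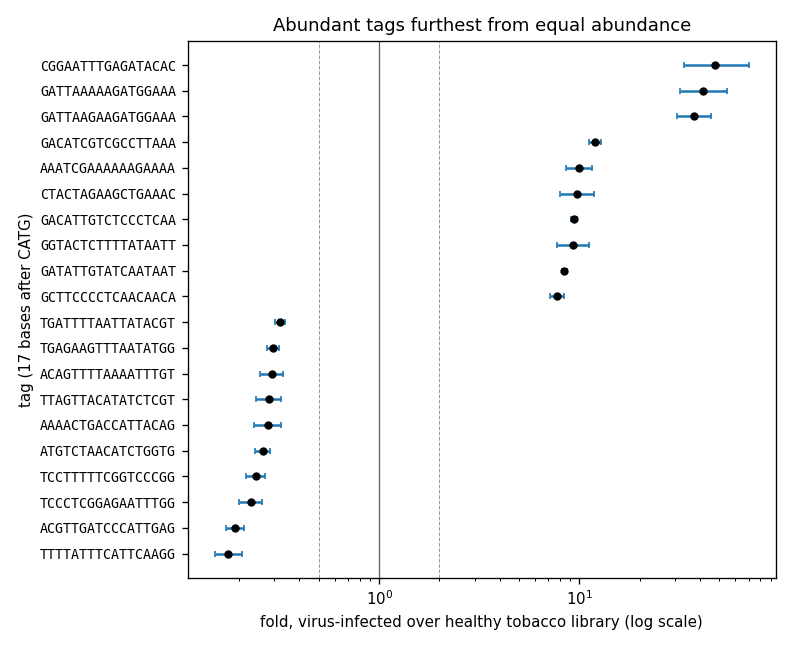
Fold of the 10 abundant tags higher and the 10 lower with the largest conservative bound (y axis), as the library from virus-infected over that from healthy tobacco (x axis, log scale), n = 1 per group. Points are folds, bars are exact 95% counting intervals, and dashed lines mark 2-fold. Higher tags run from 7.70-fold to 47.6-fold.

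Tags with a run of 8 or more A were more abundant in the library from infected plants, at 7.20% of its total against 4.12% in the healthy library (1.75-fold, 1.74 to 1.76). Of 2107 such tags measured, 585 were higher, 43 lower and 1479 not called. The tag made of A alone, AAAAAAAAAAAAAAAAA, was 1.73-fold higher, and GAAAAAAAAAAAAAAAA was 3.28-fold higher. AAATCGAAAAAAAAAAA was 11.3-fold higher. Leaving out tags that also ended in an element described below, 2100 run tags had a median log2 fold of 0.76. The medians of 10000 random lists matched on abundance lay between -0.07 and 0.10. Tags without such a run had a median log2 fold of 0.13 where they held at most 2 G or C, and -0.15 where they held 8 to 11.

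**Figure D3:**
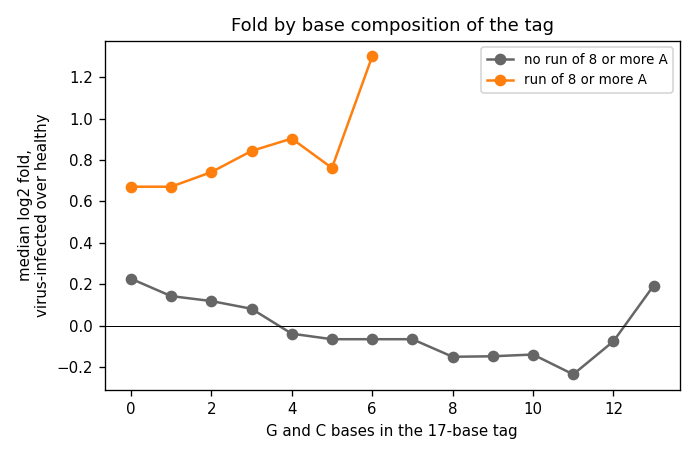
Median log2 fold, virus-infected over healthy tobacco library (y axis), of measured tags by the number of G and C among their 17 bases (x axis), for tags with and without a run of 8 or more A. Tags with a run lie above those without at each G and C number drawn for both.

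Of the 50 higher tags with the largest conservative bounds, 29 ended in at least 4 bases of a sequence element found mainly in their own library, as did 44 of the 50 lower tags. Among all 41794 measured tags, 41228 ended in neither element by that measure. Of the 50 higher tags 9 had an A run, 4 started with the complement of the 5' adapter and 13 had none of these features. For the 50 lower tags these numbers were 0, 5 and 6. A tag can have more than 1 feature. Ends of only 4 bases also occurred in the other library: TATC ended tags with 9079 counts in the library from infected plants and 5011 in the healthy one, and TTAG tags with 4206 and 8671. GGGGTTTTTTATCCGAT had 1665 counts in the library from infected plants and 0 in the healthy one, at least 530-fold higher against the floor of 3 counts, with a conservative bound of 431-fold once counting error was included. TAAAAGTGTCCGCTATC had 1504 and 0 counts, at least 479-fold higher against the floor (conservative bound 389-fold). In the other direction, GGGGTTTTTTTAGATCA had 0 and 1708 counts, at least 596-fold lower (484-fold), and TAAAAGTGTCCGCTTAG had 0 and 1307 counts, at least 456-fold lower (370-fold). Tags ending in at least the first 7 bases of TATCCGATGTTCG had 7120 counts in the library from infected plants and 13 in the healthy one. Tags ending in at least the first 7 bases of TTAGATCAGGTCG had 24 and 9973. The tag TCGGACTGTAGAACTCT, complementary to a sequencing adapter, was 4.50-fold lower in the library from infected plants, with 1912 against 8225 counts.

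**Figure D4:**
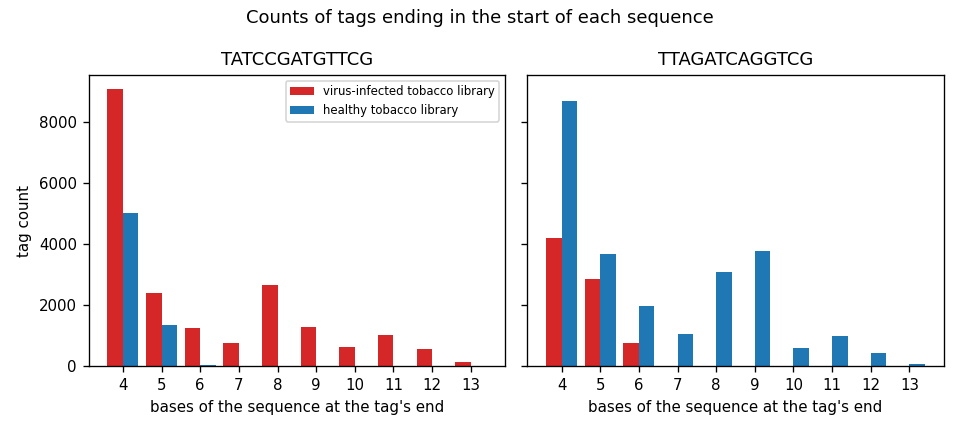
Tag counts (y axis) by the number of bases of the library-specific sequence at the end of the tag (x axis), for TATCCGATGTTCG (left) and TTAGATCAGGTCG (right), in each of the 2 libraries. From 9 bases on, each sequence had a count of 0 in the other library.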

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

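The counts of higher and lower tags stayed within 1.5 times the main values under TMM factors applied to the full totals and under median of ratios. The same held with no count minimum, removal of tags counted once and a fold of 1.5. They also did so under the alternatives added after seeing the data. Among those, folds corrected for G and C gave 4535 higher and 4348 lower tags, and merging 1-mismatch tags gave 3969 and 4172. The counts fell by construction with stricter rules. A summed count of at least 50 gave 1535 higher and 1666 lower tags, and an interval wholly beyond 2-fold gave 1334 and 955. A fold of at least 2 together with Fisher's exact test at a q under 0.001, which compares the libraries and not the conditions, gave 1537 and 1469. With tags counted once removed, 106013 different tags were left in the library from infected plants and 92822 in the healthy one. Of 27 folds of at least 2 in either direction, recomputed for tags of the report, for related tags and for GAAATCTTGGATCATTA (237-fold higher, 992 against 4 counts, chosen after its values were seen), 26 stayed there under every scaling, the G and C correction and merging. The exception, GGCTTCGCACTGTTTGA, went from 2.07-fold to 1.84-fold higher without the most abundant tag in the totals. No recomputed fold changed direction. Each scaling moved all log2 folds by the same amount, and the largest of these shifts was -0.17. For the scalings, both results were therefore largely fixed by the main folds, since a fold well beyond 2 could not cross it. The last 2 bases of the 237-fold tag match the start of the element of the library from infected plants. Its last 3 bases match the start of the healthy library's element. The scalings, the G and C correction and merging cannot show whether that end is library-specific sequence. Bounds against a count of 0, the 4 remaining tags of the library-exclusive set and the pairs of similar tags with unlike folds were not recomputed. Neither were the counts of higher and lower tags among the 588 abundant tags. Matching to genes was not made, so alternatives on the assigned total, the 3'-most site, mismatches to genes, extended transcripts and gene lists, listed beforehand, were not run. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Depth limited tags near the count minimum.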

Other observations

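The tests in this part were chosen after the results were seen, except that scaling by TMM and by median of ratios was planned before. Abundant tags of similar sequence differed less in fold, on average, than shuffled tags, with exceptions. GATTAAAAAGATGGAAA and GATTAAGAAGATGGAAA were 41.3-fold and 37.2-fold higher in the library from infected plants. GACATCGTCGCCTTAAA and GACATTGTCTCCCTCAA were 11.9-fold and 9.41-fold higher, and GGCTTCGCACTGTTTGA and GGCTTCGGTCTCTTTGA were 2.07-fold and 2.28-fold higher, the former 1.84-fold without the most abundant tag in the totals. TTCCTCAGTTGATCAAA, TTCCTCAGTTGATCAGA and TTCCTCAGTTGATCATA were 1.21-fold, 1.22-fold and 1.30-fold higher. Other pairs differed: GGATATGCTCGGCAGGG and GGATATGCTCGGCCGGA had log2 folds of 0.88 and 2.97, and TATAATTATATGAAAAA and TATAATTCTTTGATTAA 1.63 and 0.04. TTTGTATAAATTATCCT and TTTGTATTATTTATTTT had log2 folds of -1.19 and 0.05. The values of 0.04 and 0.05 are smaller than the shift of -0.17 from scaling without the most abundant tag, so their sign depends on the scaling. There were 34 pairs with at most 4 differences and an abundance ratio of at most 10, among 588 abundant tags. Of these pairs, 82.4% lay on the same side under the main scaling. That share depends on the scaling, and no shuffled share was set against it. The mean difference in log2 fold within pairs was 0.53, against 0.95 when folds were shuffled among tags of equal G and C. Of 10000 shuffles, 2 gave a mean as small. As a hypothesis, tags of similar sequence move together because they may come from related transcripts or variants of 1 transcript. Pairs sharing a tag are not independent, and the source of the tags was not tested.

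Tags counted at least 50 times in 1 library and 0 times in the other numbered 96, of which 53 were in the library from infected plants. Of the 96, 81.25% ended in at least 4 bases of their own library's element and 0 in the other's, which tests nothing because the elements were found in the tags themselves. Of the 78 tags ending in their own element, 83.3% had inserts joined to the other element in the other library, and 0 had inserts joined to that element with its bases reversed. This argues against transcripts of 1 condition for the 65 tags with such inserts and leaves a library-specific sequence joined to short inserts as a candidate explanation. Over all 96 tags, 77 had the same insert in the other library, and 90 had their own element or such an insert. Those with such an insert but without 4 element bases lie outside the 65. For the other tags ending in their own element no paired insert was found, and transcripts of 1 condition stay open. For 2 tags set aside only for an A run, and for the 4 remaining tags, transcripts of 1 condition also stay open with 1 library per group. These 4 were without 4 or more element bases, a paired insert or an A run: ATTACTTTTACTAATGA with 799 counts, ACGATTTTACTATTTTA with 597 (its last 2 bases match the start of its own library's element and its last 3 that of the other's), ATGATTTTACTGCGCGG with 74 and TGAATCTCATTGTAAAT with 71, each with 0 in the healthy library.

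The most abundant tag was 2.37-fold lower in the library from infected plants. The fold was at most 0.441 under the scalings tried, and 0.462 with the G and C correction. Those scalings shifted log2 folds by -0.17 to 0.07, against -1.25 for this tag. They could not have brought it to equal abundance, so its staying low under them excludes nothing. The tag also lay below the median log2 fold of all measured tags, -0.04, an order that a common scaling cannot change. Whether the tag came from a messenger RNA or from ribosomal RNA was not determined. G and C content is argued against as the whole cause, because 339 other tags with the same number of G and C and a summed count of at least 100 had a median log2 fold of -0.0937, and measured tags of that number without an A run had -0.15. A difference between library preparations cannot be told apart from the growth condition with 1 library per group, and a biological difference stays open as untested.

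Tags with an A run had a median log2 fold of 0.76 between the library from infected plants and the healthy one. Tags 1 mismatch from a far more abundant tag were counted separately in that median. Low G and C content is argued against as the whole cause, because tags without a run at the same G and C had a median of 0.10. Whether a library-specific sequence joined to A runs contributed was not settled. Tags ending in at least 4 bases of an element were already left out. Of the 2100 others, 2048 did not end in 2 or more bases of the element of the library from infected plants. Their median was 0.75, so the shift of the typical run tag did not rest on such ends. Removing so few tags could hardly move a median, and it does not cover single tags with such ends. Cutting sites close to the poly(A) tail may have been caught more often in 1 library: tags whose run reached the last base exceeded the others by 0.19, too little to decide, in a test rewritten after these medians were known. A biological difference between the groups was not tested and stays open.

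The adapter-like tag TCGGACTGTAGAACTCT matched the complement of the 5' adapter over all 17 bases.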
